A study of Mus musculus with 3 samples.

How the data were processed

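DNase-seq libraries of natural killer cells, taken as primary cells from male mice of the strain B6CASTF1/J (first-generation offspring of C57BL/6 and CAST mice) at 2 months of age, were analysed as 3 biological replicates of 1 group, per the labels. All 3 libraries carry the same donor label and different biosample labels, and nothing states that they came from separate animals. The labels name no sort or gate by which the cells were obtained. The aligner, the peak caller and the footprint caller are not given in the sources used here. Per the deposited descriptions, the assembly is mm10 and each list was called per library from its filtered alignments.

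For each library the authors deposited 2 lists of peaks, a list of footprints and a list of intervals with the q-value (false discovery rate, FDR) of their cut rate, which reaches up to 0.05. The deposited signal of a peak is a whole multiple of 1 step per library in 100% of peaks, within 0.05 of a step, with steps of 0.0118, 0.00651 and 0.00658 in replicates 1, 2 and 3. What a step stands for is not stated, so signal was compared as ranks within a library, as ratios within a library, or after centring on all promoters. The score in the deposited footprint lists is the constant 0.01 and was not used as a measurement. Every peak of the wider list held an FDR of 0.05 or less and every peak of the stricter list 0.001 or less. The wider list was taken as the main list and the stricter one as an alternative. That choice rested on mean peak width, 225, 208 and 204 bp in the wider lists against 227, 208 and 206 bp, since the plan asked for the list of narrower intervals. Read depth is unknown from these files, so no counting intervals are given.

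Coordinates were compared with the mouse assembly GRCm38 and a GENCODE annotation. All coordinates lay inside the reference lengths of 21 chromosomes. The annotation gave 21853 protein-coding genes with 54361 start sites. A promoter was a start site with 500 bp on each side, and it was called open where a peak overlapped it by at least 1 bp. The signal of a promoter was that of its strongest peak, and its percentile was taken among all peaks of the library. Each peak was placed by its middle, in the order promoter, exon, intron and intergenic. Peaks found in at least 2 replicates were counted within each gene body and 10 kb on each side. Of 401 entries in 21 gene lists, 400 matched the annotation. The lists and 28 sequence motifs were fixed before the data were examined, as were the tests except where stated below.

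Open promoters of each list, open in all 3 replicates, were compared with all other protein-coding genes by two-sided Fisher exact tests, and each of 4 natural killer lists was compared with each of 13 lists of other lineages (52 tests). Numbers of peaks around genes were compared with 10000 random lists matched on gene length, and promoters as an alternative with random lists matched on the CpG ratio of the promoter. The smallest two-sided p that these random lists can give is 0.0002. Motifs were searched on both strands, in footprints with at least 50% of the motif inside and in the 150 bp around the middle of each peak. Footprints were compared with windows of the same width moved within the same peak and clear of footprints, and peaks away from promoters with promoter peaks, by Fisher exact tests per replicate. P-values were adjusted by the Benjamini-Hochberg method over lists or motifs with a threshold of 0.05. Genes, footprints and peaks were the units of these tests, so the p-values describe these libraries, whose spread may be technical. Means are over the 3 replicates unless stated, with the SD. With 1 group there was no test between groups, and an exact sign-flip test of 3 replicates cannot go below p = 0.25.

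Several choices were made after the values were seen. A motif counted as different where the adjusted p was below 0.05 in all 3 replicates and all 3 went in the same direction. The comparison of replicates 2 and 3 by gene list, with random lists matched on promoter CpG ratio, and that of regions found in only 1 of them were also chosen then, as were 3 of the alternatives and the pairwise list counts under the alternatives. An alternative in which a list equalled its comparison was not counted as turned. The alternatives were other promoter widths, the better-scoring 50% of peaks, the stricter list, other overlap rules, other control windows, matching on CpG ratio or GC content, and leaving out each replicate in turn. Overlaps between peak lists were computed in Python and checked with bedtools, with 0 differences.

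The rule for named genes was fixed before the data were examined. It admits all genes of the receptor, cytotoxic effector and transcription factor lists, with the highest and lowest mean rank of promoter signal as examples. From every other list it admits up to 4 genes with the highest mean rank among those open in all 3 replicates and up to 2 without a peak in any, in alphabetical order. It also admits the 10 genes with the most peaks and the 10 with the highest promoter rank.

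The procedures were tested on simulated data. For open promoters, 99 of 100 lists of 20 genes made with 90% open against 50% were called, and 2 of 100 lists made without a difference, among 21853 genes. For peaks around genes, 20 of 20 lists with 4 peaks per gene added and 0 of 20 unchanged lists were called. Smaller differences were not simulated, and the simulated open promoters did not depend on CpG ratio. For motifs in 20000 windows, 1 of 1 written motif and 0 of 27 others were called, with a log2 ratio of 2.00 recovered for a set value of 2. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0, matplotlib 3.10.9 and bedtools 2.31.1 were used.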

Results

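Natural killer cells, lymphocytes that kill infected or transformed cells, were profiled in 3 DNase-seq libraries of 1 group, adult male B6CASTF1/J mice. DNase I cuts DNA that is free of nucleosomes, so clusters of cuts mark accessible sites (peaks), and short protected stretches inside them (footprints) mark DNA covered by bound proteins. Replicates 1, 2 and 3 held 40484, 84564 and 81854 peaks, which covered 8.93, 17.3 and 16.6 Mb with median widths of 220, 200 and 200 bp. They held 101990, 239483 and 222990 footprints, with median widths of 9, 10 and 10 bp, of which 85.3% ± 1.69 (SD, n = 3) lay inside peaks. Read depth is unknown from the files used here. The genome covered at an FDR of 0.05 was 16.1, 32.3 and 30.9 Mb. The question asked here was which genes and sequence elements lie open in these cells, and how alike the replicates are. The labels give 1 donor label for all 3 libraries, so the spread between them may be technical.

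Genes of the natural killer programme had open promoters in these cells. Of 22 cytotoxic effector genes, 19 (86.4%) had a promoter peak in all 3 replicates, as had 20 of 22 natural killer transcription factor genes (90.9%), against 51.3% of other protein-coding genes (exact Fisher tests, adjusted p = 0.00193 and 0.000465). Cytokine receptor and signalling genes were open in 21 of 22 cases (95.5%, exact test, adjusted p = 8.6e-05). Of 25 natural killer receptor genes 17 (68.0%) were open, and of 20 trafficking genes 13 (65.0%), which did not pass the exact test against all genes (adjusted p = 0.136 and 0.311). Both lists consist largely of CpG-poor promoters. Random lists matched on promoter CpG ratio had medians of 20% and 30% open, against which both passed (permutation test, adjusted p = 0.0007, from the smallest p the lists can give). All random lists were drawn from all protein-coding genes outside the list, sensory receptor genes included. Of 1134 such genes with symbols that start with Olfr and 331 with Vmn, 3 and 1 were open in all 3 replicates. How far they lower the matched medians was not measured. Against all genes, the receptor result depended on the setting. With the better-scoring peaks alone, the open share of receptor genes turned below that of other genes. It passed as higher with the widest promoters, with a peak in any replicate, and when the replicate with the fewest peaks was left out. All 28 housekeeping genes and 15 of 16 immediate early genes were open as well.

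Among cytotoxic effectors, the strongest promoters belonged to Lamp1, a granule membrane protein, at percentile 92.9 ± 6.90 of peak signal in its library (mean ± SD, n = 3), and Prf1, the pore-forming protein perforin, at 90.5 ± 3.75. Prf1 lies on chromosome 10 from 61297833 to 61304680 (mm10) and its promoter peak had signals of 4.05, 6.01 and 10.2 in replicates 1, 2 and 3. Rab27a, needed for granule release, stood at percentile 88.8 ± 5.43 and the chemokine gene Ccl4 at 86.7 ± 4.85. Gzmb, which encodes granzyme B, stood at 85.5 ± 7.06 (chromosome 14, 56258838 to 56262260), Nkg7 at 83.9 ± 5.40, and Ifng, which encodes interferon gamma, at 71.1 ± 8.08. The lowest were Ctsw at 62.6 ± 20.1 and Gzmk at 22.2 ± 18.2. Gzma, Gzmc and Gzmm had a promoter peak in replicate 3 and in no other library.

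The highest natural killer transcription factor promoters ranked above the highest receptor promoters. These ranks were not matched on promoter CpG ratio, whose median was 0.643 in the transcription factor list and 0.185 in the receptor list. Klf2, a factor of lymphocyte quiescence and trafficking, stood at percentile 99.3 ± 0.670 (SD, n = 3) on chromosome 8 from 72319033 to 72321656, with signals of 9.59, 27.2 and 28.4. Ets1 followed at 97.1 ± 1.40, Id2, an inhibitor of E proteins, at 95.5 ± 1.62, and Runx3 at 94.7 ± 2.43. Eomes, a T-box factor of natural killer identity, stood at 73.3 ± 8.86, and Zeb2 and Tox2 were lowest at 65.0 ± 7.29 and 55.7 ± 12.1. Tbx21, which encodes T-bet, had a promoter peak in replicates 2 and 3 (1.11 and 1.60) but not in replicate 1. Zfp683 had none.

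Receptor genes spanned a wide range. Sh2d2a, an adaptor, was highest at percentile 86.2 ± 4.26, followed by Ncr1, which encodes the activating receptor NKp46, at 83.0 ± 6.61 (chromosome 7, 4337724 to 4345164). The signalling chain Fcer1g stood at 80.3 ± 4.30 and the Fc receptor gene Fcgr3 at 77.4 ± 4.12. Klrc1 and Klrc2, which encode NKG2A and NKG2C, were lowest at 27.8 ± 7.30 and 24.5 ± 10.3. Cd226, Klrb1c, Klrd1 and Slamf7 were open in 2 replicates, and Klrb1f, Klrg1, Klri1 and Klri2 in none. Of 11 genes of the Ly49 receptor family, Klra5 and Klra1 were open in all 3 replicates, at 27.9 ± 16 and 19.8 ± 14.9, and the other 9 in none. That share, 18.2%, was below that of other genes (exact Fisher test, adjusted p = 0.0480), but not below random lists matched on CpG ratio, whose median was 9.09% (permutation test, adjusted p = 0.861).

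Promoters of other lineages were mostly closed. None of 20 neutrophil genes was open in all 3 replicates, and 18 of them, Camp and Cebpe included, had no peak in any (exact test, adjusted p = 5.88e-06). Hepatocyte and neuronal genes were each open in 1 of 18 cases, Trf and Grin1 (exact tests, adjusted p = 0.000224 for each list). Of 18 muscle genes 2 were open, Mylpf and Ryr1, and of 17 erythroid genes 2, Tspan33 and Epor, while Alas2 and Epb42 had no peak (exact tests, adjusted p = 0.0013 and 0.00196). Monocyte and macrophage genes were open in 3 of 22 cases, Cd68, Cebpa and Spi1, with no peak at Adgre1 or C1qa (exact test, adjusted p = 0.00112). Of 12 mast cell and basophil genes only Kit was open (exact test, adjusted p = 0.00482), of 15 megakaryocyte and platelet genes 3, Itgb3, F2rl2 and Itga2b (adjusted p = 0.03), and of 20 endothelial and stromal genes 5, with Pdgfra and Pecam1 highest (adjusted p = 0.0355). All of these 9 lists also lay below the median of random lists matched on CpG ratio. The neutrophil and neuronal lists alone passed that test (permutation tests, adjusted p = 0.05, just under the threshold, and 0.0007). Without replicate 1, monocyte and macrophage genes (36.4%) and endothelial and stromal genes (35%) no longer passed the exact test. Endothelial and stromal genes also failed it with promoters of 1000 bp (30%) and 2500 bp (35%) on each side, and megakaryocyte genes with 2500 bp (33.3%). With a peak in at least 1 replicate, monocyte and macrophage (45.5%), erythroid (35.3%), mast cell (33.3%), endothelial and stromal (40%) and neuronal genes (44.4%) failed it.

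Lymphoid and antigen-presenting lists were not separated from all other genes by this test. T cell genes were open in 6 of 20 cases, with Cd28 highest at percentile 82.5 ± 10.1 (SD, n = 3) and Lef1 at 70.0 ± 8.28, and with no peak at Cd4 or Cd8a (exact Fisher test, adjusted p = 0.0951), although in the better-scoring 50% of peaks, at 10%, they passed as lower. Of 18 dendritic cell genes 7 were open (exact test, adjusted p = 0.386), led by the antigen presentation genes H2-Aa, H2-Ab1 and Cd74. Progenitor genes were open in 9 of 16 cases (exact test, adjusted p = 0.845), led by Meis1 and Hoxa10. B cell genes were open in 10 of 20 cases, with Ebf1 highest at 76.6 ± 17.2 and no peak at Vpreb3 (exact test, adjusted p = 1), but random lists matched on CpG ratio had a median of 30%, and against those the B cell list was higher (permutation test, adjusted p = 0.05, just under the threshold). In the better-scoring 50% of peaks, B cell genes, like T cell genes, passed the exact test as lower than other genes.

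The transcription factor list had a higher share of open promoters than each of the 13 lists of other lineages, the cytotoxic list than 12, the receptor list than 10 and the Ly49 list than none (exact Fisher tests, adjusted p below 0.05 over 52 tests). Progenitor genes were not separated from cytotoxic genes (exact test, adjusted p = 0.09). B cell, dendritic and progenitor genes were not separated from receptor genes (exact tests, adjusted p = 0.306, 0.0999 and 0.623). The pairwise tests did not match lists on promoter CpG ratio. Its median was 0.643 for transcription factor genes, for which matched random lists had 63.6% open. Among lists of other lineages it ranged from 0.161 (mast cell and basophil) to 0.582 (progenitor). CpG content may thus add to the transcription factor separations, which was not tested. The cytotoxic and receptor lists were CpG-poor, at 0.204 and 0.185, with 22.7% and 20% open in matched lists. Part of these separations also rests on replicate 1. Without it the transcription factor list, at 95.5%, was higher than 11 lists, not B cell (85%) and progenitor genes (68.8%). The cytotoxic list, at 86.4%, was then higher than 9, not B cell, progenitor, dendritic (61.1%) and T cell genes (55%), and the receptor list, at 80%, than 9, not these 4.

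**Figure D1:**
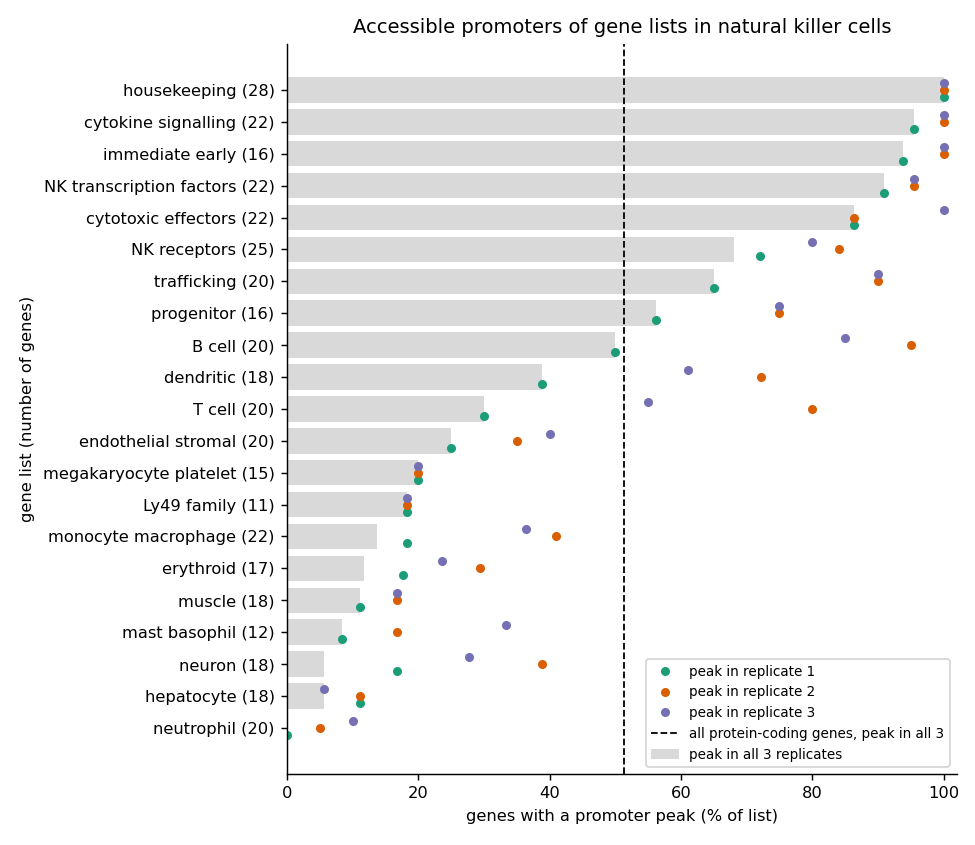
Percent of the genes of each list with a promoter peak. Bars give genes open in all 3 replicates, points each replicate alone, and the dashed line all protein-coding genes (51.3%). The cytokine, transcription factor and cytotoxic lists lie above 86% and the neutrophil list at 0%, while B and T cell genes differ most between replicates.

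B and T cell genes differed most between replicates in how many promoters were open, and B cell genes differed most in signal between replicates 2 and 3. They were open in 10, 19 and 17 of 20 cases in replicates 1, 2 and 3, and T cell genes in 6, 16 and 11, while cytotoxic genes were open in 19, 19 and 22 of 22. The promoter of Pax5, a factor of B cell identity, stood at percentile 32.8, 96.1 and 92.4 of its library, Ebf1 at 57.5, 90.8 and 81.5, and Cr2 at 56.5, 91.3 and 80.5. In log2 signal centred on all promoters open in all 3 replicates, B cell genes were higher in replicate 2 than in replicate 3 by a median of 1.01, in 17 of 17 genes open in both. Cytotoxic genes went the other way, with a median of -0.72 and 2 of 19 genes above 0, and so did receptor genes, with -0.54 and 1 of 20, while cytokine signalling genes differed by -0.14 with 4 of 22 above 0 (permutation test, adjusted p = 0.0359). The B cell, cytotoxic and receptor medians each lay beyond all 10000 random lists matched on CpG ratio (permutation test, p = 0.0002, the smallest they can give, adjusted p = 0.000867 over 13 lists). Dendritic genes were higher by 0.31 in 8 of 11 genes (permutation tests, adjusted p = 0.0149), T cell genes differed by -0.12 (adjusted p = 0.349) and housekeeping genes by -0.02 (adjusted p = 0.597). The T cell median hides a split, with an SD of 0.65 over the 11 genes open in both and 4 of them above 0. It leaves out T cell genes with a peak in replicate 2 and none in replicate 3, where 16 and 11 were open. Within libraries, a B cell promoter ranked above a cytotoxic one in 13%, 52.8% and 20.3% of gene pairs in replicates 1, 2 and 3. This comparison of 2 libraries was chosen after the values were seen. Without replicate 1, 85.0% of B cell genes, 80% of receptor genes and 90% of trafficking genes were open in both other replicates, and these 3 lists then passed the test against other genes, where the B cell list stood at 50% without replicate 2 or without replicate 3.

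**Figure D2:**
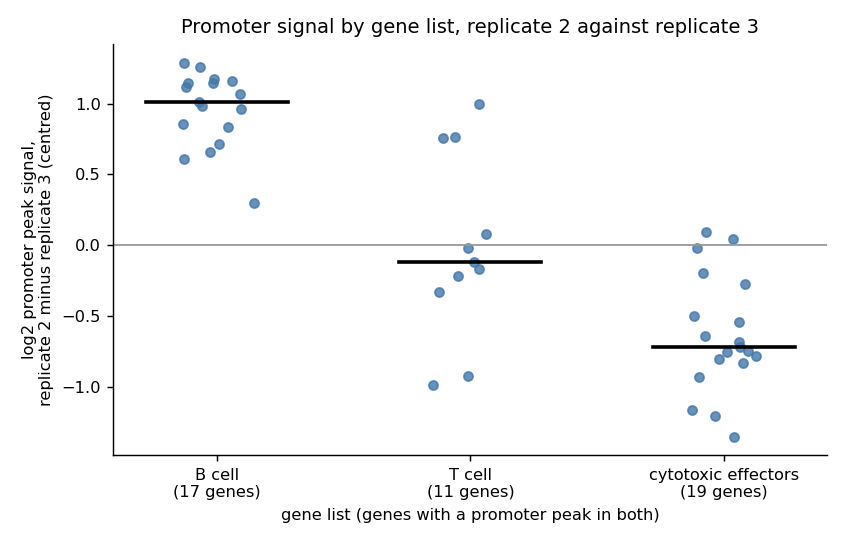
Log2 promoter peak signal in replicate 2 minus replicate 3, centred on all promoters open in all 3 replicates, for genes open in both. Points are genes and bars medians. All 17 B cell genes lie above 0 (median 1.01), and 17 of the 19 cytotoxic genes below (median -0.72).

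Regulatory sites were dense around genes of 7 lists, natural killer lists among them. Transcription factor genes had a median of 12 peaks, found in at least 2 replicates, within the gene and 10 kb on each side, where random lists of equal gene length had 3. Cytokine signalling genes had 7 against 3, trafficking genes 7 against 2.5 and immediate early genes 9.5 against 2 (permutation tests, each p = 0.0002, the smallest the lists can give, adjusted p = 0.00105). Cytotoxic genes had 5 against 2 (permutation tests, adjusted p = 0.00168), receptor genes 5 against 2 (adjusted p = 0.0222) and B cell genes 6 against 3 (adjusted p = 0.007). Within the groups, Bach2 had 42 peaks, Runx1 26, Ikzf1 23, Cd247 14 and Rab27a 10. These counts of single genes were not set against gene length. Of 30430 regions found in 2 replicates, 29389 were those of replicates 2 and 3, where 19 and 17 of 20 B cell promoters were open. Which cells the counted peaks came from was not tested. Ly49 genes had 1 against 3 (permutation test, adjusted p = 0.302), and none of the other lists passed at this setting. Dendritic genes passed with 50 kb on each side (13 against 7) and with lists also matched on CpG ratio (4.5 against 1.5), and housekeeping genes, at 4 against 2, passed with 50 kb (10.5 against 6.5). Without replicate 2 or without replicate 3, housekeeping genes (3 against 1) passed as higher and neuronal genes (0 against 2) as lower. Receptor genes did not pass when any replicate was left out (medians 3 to 4), nor did B cell genes without replicate 2 or without replicate 3 (2 against 1.5). In those 2 settings transcription factor genes had 6.5 against 2, cytokine signalling genes 4 against 2 and trafficking genes 3.5 against 1.5, which still passed. With 50 kb on each side the 7 lists passed, at medians of 12 to 18.5.

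Across all protein-coding genes, Gm20388 held the most peaks (404), followed by Fgfr2 (103), Foxp1 (74), Gse1 (55), Bach2 (42), Mid1 (41), Gm37240 (40) and Arid1b, Camta1 and Zmiz1 (39 each). Gm20388 (chromosome 8, 119910841 to 124345722), Fgfr2 and Gm37240 are very long gene models that span other genes, and the Fgfr2 promoter was open in replicate 3 alone. Foxp1 encodes a forkhead factor of lymphocytes. Whether sequence at the genes with the most peaks or the highest promoter rank is unique in the genome was not checked. None of the 10 genes with the highest promoter rank is in a gene list used here. Dynlt1b (chromosome 17, 6430112 to 6436296), which encodes a dynein light chain, had signals of 31.3, 72.7 and 74.9, followed in mean rank by Add3, Dnpep, Esrra, Odf2, Mplkip with Sugct, Sde2, and Nsun2 with Srd5a1, where each of the 2 pairs shares a peak.

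Peaks concentrated at promoters, which held 26.0% ± 8.36 of them (SD, n = 3) on 1.30% of the genome. Exons held 8.18% ± 0.0976 on 4.36%, introns 37.7% ± 5.37 on 40.7% and intergenic sequence 28.2% ± 2.96 on 53.6%. The promoter share was 35.6% in replicate 1, the smallest list, and 20.9% and 21.4% in replicates 2 and 3. With promoters of 2500 bp on each side of the start site it was 39.9%, over 1.5 times higher.

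Among the motifs in footprints, that of CTCF, which organises chromatin loops, was enriched most. The CTCF motif lay in 2.46% ± 0.0608 of footprints and 0.0367% ± 0.0125 of control windows in the same peaks, a log2 ratio of 6.11 ± 0.50 (SD, n = 3). NRF1 followed at 4.75 ± 0.28, the CRE element at 4.54 ± 0.69, the GC box of SP and KLF factors at 3.68 ± 0.31 and the ETS motif at 2.91 ± 0.56. The RUNX motif was enriched by less, at 0.91 ± 0.41, as were the CACCC box of KLF factors at 0.98 ± 0.20 and IRF at 0.61 ± 0.11 (exact Fisher tests, largest adjusted p of 3 replicates 4.96e-06, 6.99e-07 and 0.0122). Of 28 motifs 11 were more frequent in footprints and 2 less frequent, the octamer of POU factors at -0.72 ± 0.28 and the CCAAT box of NF-Y at -0.30 ± 0.09. The T-box motif, bound by T-bet and Eomes, did not pass in any replicate (0.13 ± 0.15). Against GC-matched windows outside peaks, NF-Y turned to 0.65 and the E-box of ZEB and E proteins, 0.39 in the same peaks, turned to -0.28, PU.1 turned to 1.42 and MEF2 rose to 2.11, all past the threshold, and the CACCC box at 0.49 and the octamer, turned to 0.78, no longer passed. There ETS rose to 5.75, RUNX to 1.97 and IRF to 1.85, and the GC box fell to 2.11. In footprints outside promoters the E-box stood at 0.74, and STAT at -0.57 passed as less frequent, and IRF at 0.61 and the octamer at -0.40 did not pass. Without replicate 1, EBF1 (1.94), NF-kB (0.66) and C/EBP (1.68) passed as more frequent and GATA (-0.62) as less, and without replicate 3 AP-1 (-0.57) as less.

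Accessible sites away from promoters differed from promoter peaks in most motifs. The RUNX motif lay in 9.98% ± 0.860 of distal peaks and 3.21% ± 0.242 of promoter peaks, a log2 ratio of 1.64 ± 0.06 (SD, n = 3). CTCF stood at 3.16 ± 0.38, the T-box motif at 1.80 ± 0.19, AP-1 at 1.66 ± 0.10, GATA at 1.56 ± 0.08 and TCF and LEF at 1.38 ± 0.12. Promoter peaks carried YY1 (-4.36 ± 0.52), NRF1 (-3.97 ± 0.28), the GC box (-3.03 ± 0.16), the ETS core (-2.55 ± 0.07) and CRE (-2.16 ± 0.15). Of 28 motifs 12 were more frequent in distal and 9 in promoter peaks, in all 3 replicates. For the T-box motif the largest adjusted p was 4.78e-29 and for GATA 4.5e-19 (exact Fisher tests). With distal and promoter peaks matched on GC content the T-box ratio was 1.01, RUNX 0.84 and AP-1 1.11, TCF and LEF 0.41, YY1 -2.54, NRF1 -2.02 and the GC box -0.99, all past the threshold, while GATA at 0.39, MEF2 at 0.85, HNF4 at 0.11 and C/EBP at -1.78 no longer passed and IRF turned to -0.35. Under that matching NFIL3 (-2.58), TATA (-1.48), STAT (turned to -0.66) and NF-kB (turned to 0.38) newly passed. With promoters of 2500 bp on each side the T-box ratio was 1.20 and GATA 1.01, STAT (0.29) and the octamer (0.58) newly passed and HNF4 (0.64) did not. Without replicate 1 the octamer (0.55) passed as more frequent in distal peaks, and without replicate 3 NFIL3 (-1.38) in promoter peaks.

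**Figure D3:**
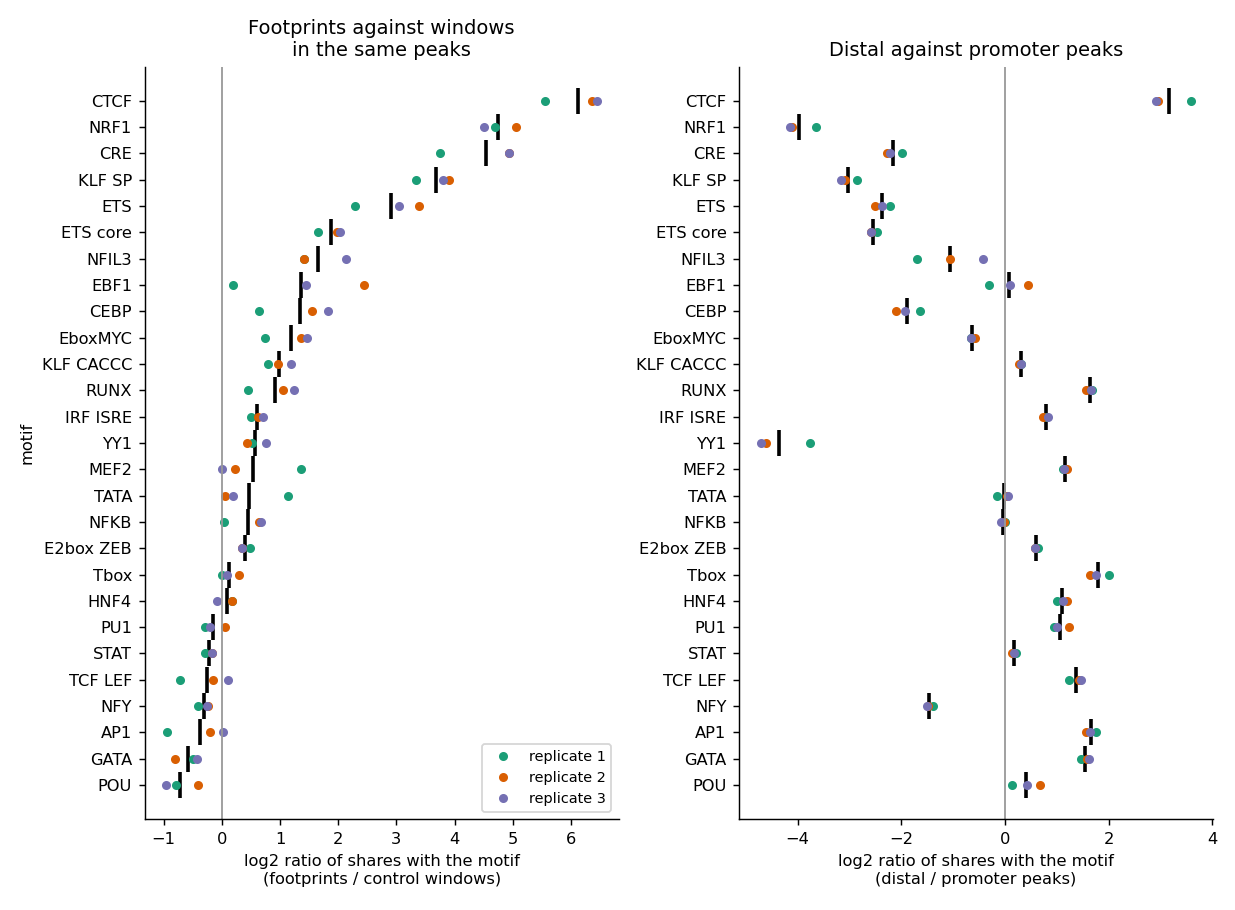
Log2 ratio of the share of intervals with each motif, in footprints against control windows of the same peaks (left) and in distal against promoter peaks (right). Points are replicates and bars their means. CTCF leads on the left at 6.11 and on the right at 3.16, where the T-box motif lies at 1.80.

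Peaks on the X chromosome were weaker and sparser than on any autosome. Their median signal was 0.596 ± 0.0338 (SD, n = 3) of the autosomal median, 0.630, 0.594 and 0.563 in replicates 1, 2 and 3, where the means of the 19 autosomes ranged from 0.864 to 1.20. X held 10.9 ± 3.90 peaks per Mb, and the autosomes 20.5 to 46.0. Promoter peaks alone gave a ratio of 0.535 and peaks away from promoters 0.571. Chromosome Y stood at 0.288. Chromosome 11 was highest in both signal and peaks per Mb. No value was adjusted for gene density. X has 948 protein-coding genes on 163 Mb, close in density to chromosomes 12 (642 on 117 Mb) and 18 (511 on 87.5 Mb). Those held 23.7 and 22.2 peaks per Mb, with signal ratios of 0.889 and 0.893. These values argue against low gene density alone as the cause on X. The 3 X ratios lay below every autosome in every replicate, and no p is given, since 3 replicates allow none below 0.25 in an exact sign-flip test.

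**Figure D4:**
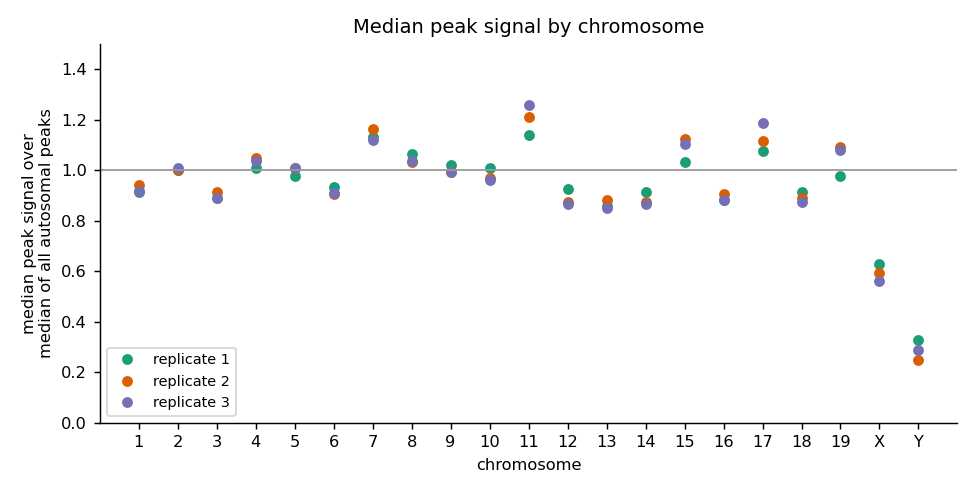
Median peak signal of each chromosome divided by the median of all autosomal peaks, for each replicate. X lies at 0.563 to 0.630 in the 3 replicates and Y lower, while the means of the autosomes range from 0.864 to 1.20.

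Regions found in all 3 replicates were richer in promoters than the rest. The 3 lists merged into 98643 regions, of which 34969 (35.5%) were found in all 3 replicates, 30430 in 2 and 33244 in 1. Promoters made up 34.8% of regions found in all 3, 9.47% of those found in 2 and 11.5% of those found in 1. Of the regions in 2 replicates, 29389 were missing from replicate 1. Peaks of replicate 1 were found in replicates 2 and 3 in 91.0% and 91.2% of cases, while replicate 1 held 43.8% and 45.4% of theirs. Replicates 2 and 3 held 79.0% and 81.7% of each other. Over the 6 ordered pairs the mean was 72.0% ± 21.8, where peaks placed at random gave 1.14%. Across the regions in all 3, log2 signal correlated with Pearson r of 0.916 (replicates 1 and 2), 0.931 (1 and 3) and 0.957 (2 and 3) and Spearman rho of 0.895, 0.921 and 0.947, given as description, since regions are not independent replicates. Signal in these regions was higher than in replicate 1 by a median log2 of 0.92 in replicate 2 and by more in replicate 3, so signals printed for a promoter are not on a common scale across libraries. Regions of both other replicates that were missing from replicate 1 were weak, with a median percentile of 38.2 against 77.0 for those present, and 98.1% of the strongest 20% were present. Footprints overlapped in 50.4% of cases on average, and in 27.8% with equal numbers drawn at random. The lower value says nothing about agreement, since a random draw removes partners from the longer lists and so lowers overlap by construction. Inside peaks shared by a pair, 57.4% ± 12 of footprints overlapped, against 39.3% ± 6.56 after they were moved at random within their peaks (SD over 6 ordered pairs).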

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

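Of 880 alternatives over 172 results, 765 left the result as it was. That meant the same direction and side of the threshold, or for values without a test a value within 1 SD. For 12 counts of lists or motifs it meant a count within a fixed margin of the main one. Such a count could differ and still be tallied as unchanged, as were 77 of 86 alternatives for counts. In 30 the result was no longer past the threshold, in 30 it newly passed, in 21 a value or count moved and in 34 the direction turned. Of these, 183 leave out 1 of 3 replicates from a mean of 3 (named genes, annotation shares and the X ratio), and the mean of 2 of 3 values always lies within 1 SD of the mean of 3, so they say nothing about stability. Nor do those that leave a replicate out of a motif called in all 3, which then cannot lose its call. Of the alternatives, 3 were chosen after the data were seen: footprints drawn at random in equal numbers, X peaks away from promoters, and replicate 1 alone for promoters. An equal number of footprints taken by score was not run, as the score is constant. HNF1 gave no ratio under any setting, nor did NFIL3, YY1 and C/EBP in footprints against GC-matched windows. The cytotoxic, transcription factor and cytokine lists kept their direction and side of the threshold under all 10 alternatives for promoters and all 5 for peaks around genes, as did CTCF, NRF1 and RUNX motifs in footprints, and these and T-box in distal peaks, under the 2 alternatives in each that do not leave out a replicate. Peak overlap ranged from 59.4% to 81.0% over its alternatives. Except where stated, the cause of a change was not tested. Read depth is unknown, so the part it plays in what replicate 1 lacks was not measured.

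Footprint overlap fell to 27.8% with random equal numbers, by construction, since the draw removes partners from the longer lists. Shares of peaks moved with promoter width, by construction, since a wider promoter takes peaks from the other classes: exons held 6.47% at 1000 bp on each side, and at 2500 bp promoters held 39.9%, exons 5.13%, introns 29.7% and intergenic sequence 25.2%. In the better-scoring 50% of each list they held 38.0%, 7.04%, 30.6% and 24.4%. The X ratio was 0.535 over promoter peaks. Peak signal correlation ranged from 0.916 to 0.957 when each replicate was left out.

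Among promoter lists, 2500 bp on each side gave 80% of receptor genes (then past the threshold), 65.0% of B cell and 55.6% of dendritic genes, the last 2 turning above other genes without passing. Endothelial and stromal genes lost their call at 1000 bp (30%), 2500 bp (35%), with a peak in at least 1 replicate (40%) and without replicate 1 (35%). Others did so at 2500 bp (megakaryocyte), with a peak in at least 1 replicate (monocyte and macrophage, erythroid, mast cell, neuronal) and without replicate 1 (monocyte and macrophage). A peak in at least 1 replicate gave 84.0% of receptor genes, 95% of B cell genes and 90% of trafficking genes (all then past the threshold), 80% of T cell and 72.2% of dendritic genes, with 8 lists more and 5 fewer open than other genes, where the main setting gave 5 and 10. In the better-scoring 50% of peaks, 15% of B cell and 10% of T cell genes were open, both then past the threshold as below other genes. There 44.0% of receptor genes and 25% of progenitor genes were open, and both lists turned from above other genes to below them. Progenitor genes also turned below in the stricter list, at 43.8%. Against lists matched on CpG ratio, 68.0% of receptor genes stood above a median of 20%, 18.2% of Ly49 genes above 9.09%, 50% of B cell genes above 30% and 38.9% of dendritic genes above 33.3%, with 8 lists more open and 2 fewer. Here the construction shows a cause, since the comparison genes then have CpG-poor promoters. How far sensory receptor genes among them, nearly all without a peak, add to it was not measured. Leaving out each replicate gave 68.0% to 80% of receptor genes, 50% to 85.0% of B cell genes, 38.9% to 61.1% of dendritic genes, 65.0% to 90% of trafficking genes (past the threshold without replicate 1), and 5 to 8 lists more open. Pairwise, the number of other lineages below the cytotoxic list ranged from 9 to 12, below transcription factors from 11 to 13 and below receptors from 9 to 10, each lowest without replicate 1.

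Peaks around genes, with 50 kb on each side, had a median of 2 for Ly49 genes against 7 (then past the threshold, and 1 list with fewer peaks) and of 7 for megakaryocyte genes against 6. Dendritic genes (13 against 7) and housekeeping genes (10.5 against 6.5) also newly passed there. With lists matched on gene length and CpG ratio the medians were 1.5 against 0.5 for monocyte and macrophage genes, 0.5 against 0 for neutrophil genes and 1 against 0 for mast cell genes, none past the threshold, while dendritic genes (4.5 against 1.5) newly passed. Leaving out each replicate gave medians of 3 to 4 for receptor genes and 2 to 6 for B cell genes, and 0 to 1 lists with fewer peaks.

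In footprints against GC-matched windows outside peaks, the log2 ratio turned to 0.61 for AP-1, 0.37 for STAT, 0.65 for NF-Y, -0.28 for the E-box of ZEB and E proteins, 0.10 for TCF and LEF, 1.42 for PU.1 (then past the threshold), -0.050 for HNF4 and 0.78 for POU, with 1 motif less frequent in place of 2, and MEF2 newly passed at 2.11. In footprints outside promoters TATA turned to -0.43. Between distal and promoter peaks matched on GC content it turned to -0.35 for IRF, -0.66 for STAT and 0.38 for NF-kB (both then past the threshold) and -0.55 for POU, and with 2500 bp promoters to -0.030 for EBF1 and 0.15 for TATA. Leaving out each replicate gave -0.11 to 0.27 for EBF1 and -0.059 to 0.045 for TATA.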

Other observations

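Genes of the sensory receptor families lacked a promoter peak almost without exception. Whether sequence at their start sites is unique in the genome was not checked, so lost reads and closed promoters cannot be told apart. Of 1134 genes with symbols that start with Olfr, 3 had a promoter peak in all 3 replicates and 1120 in none, and of 331 that start with Vmn 1 and 328. Among regions away from promoters, those found in replicate 2 alone (15172) and those found in replicate 3 alone (12555) differed in motifs. RUNX sites lay in 6.12% and 11.7% of them, T-box sites in 0.824% and 2.37%, and AP-1 sites in 4.12% and 8.57%. EBF1 sites lay in 1.47% and 0.350%, PU.1 sites in 5.45% and 2.97% and octamers of POU factors in 1.79% and 0.709%, with 1 library on each side. CTCF sites lay in 2.46% and 1.25% and the E-box of ZEB and E proteins in 16.9% and 13.9%.

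The tests of the B cell and X patterns below were chosen after the result was seen, and the Ly49 test before. With 1 group, no explanation was tested by comparing groups.

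B cell promoters stood higher in replicate 2 than in replicate 3, relative to all promoters. A difference in depth or enrichment between the libraries alone is argued against, since cytotoxic genes, also with CpG-poor promoters, moved the other way, with a median log2 difference of -0.72. A candidate explanation is a larger share of B lineage cells in replicate 2, as EBF1 sites were 4.19 times as frequent in regions of replicate 2 alone as in those of replicate 3 alone. CTCF sites were also more frequent there, so cell share need not be the whole difference between these regions, and Pax5 and Ebf1 stood at percentile 96.1 and 90.8 in replicate 2 and 92.4 and 81.5 in replicate 3. The labels name no sort or gate, none of the 20 genes is in another list, and how many of them natural killer cells use themselves is not known from these data, so a difference within natural killer cells stays open and was not tested.

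Peak signal on X lay at 0.596 of that on autosomes. Among CpG-rich promoters open in all 3 replicates (188 genes on X, 8059 on autosomes) the ratio was at most 0.599. That does not settle whether X has fewer strong promoters. Being CpG-rich does not fix strength, and weaker promoters on X would lower this ratio too. A single copy of X against 2 of each autosome in these male mice may also account for the lower signal. The mean ratio of those promoters was 0.595 ± 0.0059, which cannot tell the 2 explanations apart. It lies above the ratio of 1 copy to 2, and what fills the difference was not tested.

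Few Ly49 promoters held a peak, 2 of 11. Reads from near-identical copies, left out or split, remain open: the median share of 31-mers that are unique in the genome was 78.8% at Ly49 start sites and 98.3% at those of natural killer receptors, a gap of 19.5 points, short of the 20 set beforehand. Single genes went both ways. Klra17 (97.2% unique), Klra2 (96.3%) and Klra7 (91.5%) had no peak in any replicate, while Klra5 (69.7%), Sh2d1b1 (64.9%), Fcgr3 (57.2%) and Klrc2 (18.8%) had one in all 3. These were chosen after their values were seen, as genes in which uniqueness did not go with a peak. In others it did: Klra8 (42.0%), Klra9 (47.0%), Klra4 (56.3%) and Klra10 (64.3%) had none, and Klra1 (91.3%) had one in all 3. Such picked genes decide nothing. For the family as a whole lost reads and closed promoters cannot be told apart, since the gap met neither bound set beforehand, and differences between the CAST genome and the reference were not tested.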
